A study of Mus musculus with 24 samples.

How the data were processed

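Bulk RNA sequencing was carried out on hearts of male and female mice of 3 inbred strains, C57BL/6J, CAST/EiJ and NZO/HlLtJ, that ate a diet labelled as 10% or 44% fat, each with fiber, which the treatment protocol calls control and high fat, high sugar. Per the labels, the diets began at week 6 and tissue was taken at week 15. The labels describe a polyadenylated RNA library kit, added spike-in transcripts, paired-end reads of 100 bases and a target number of read pairs per library. The 24 libraries form 12 groups of strain, sex and diet with 2 libraries in each. Group membership was taken from the titles and characteristics in the labels. Replicate numbers were given in accession order, so they name libraries and pair none. The labels give no statement that the 2 libraries of a group came from separate animals, so the p-values measure the spread between these samples, part of which may be technical.

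The authors deposited a table of expected counts per gene, which are estimated read counts that need not be whole. Of its values, 19.3% were not whole at a tolerance of 1e-06, and each of the 20961 listed genes was above 0 in at least 13 of the 24 libraries. The authors also deposited a matrix of variance-stabilized values on a log2-like scale for the same genes and libraries. GRCm38 and DESeq2 are named in the submitters' processing notes without a version or a role. The aligner, the program that counted the reads, its handling of strand and the release of the gene annotation are not given in the sources used here. Positions were taken from the GRCm38 gene annotation (GENCODE M21): of the 20961 identifiers, 20840 were found there on the same chromosome, 16870 with the same start and end. No spike-in transcript was analysed here. Reads assigned to genes with near-identical copies, to overlapping genes and to antisense partners such as Tsix and Xist could have been divided in ways that differ between strains, and some of these genes are named below as uncertain. Other annotated genes also overlap genes named below without such a mark. They include Mhrt at Myh7, Ifi203 and Ifi211 at Mndal, Tmem59 at Tceanc2, Mrpl44 at Wdfy1, F2rl2 at Iqgap2, Fndc9 at Cyfip2, Olfr56 at Tgtp2 and Thra at Nr1d1, and genes with only a predicted name at several others.

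Total counts per library ranged from 30205073 to 52254058. Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 12 groups with a minimum count of 10 and a minimum total of 15, which left 17203 genes and removed 3758. Library sizes were scaled by TMM factors, which lay between 0.954 and 1.06. One quasi-likelihood model with a mean for each of the 12 groups was fitted to all 24 libraries with robust estimation, so that all comparisons share one estimate of the spread per gene. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 16 contrasts were the diet effect in each strain, the 3 strain differences, the differences of the diet effect between strains, the sex difference, and the differences of the sex effect between strains and between diets, over all strains and in each strain. In each contrast the groups were weighted equally. Fold changes are on the log2 scale with standard errors (SE), and levels are CPM (counts divided by the TMM-scaled library total, times 1e6) as mean ± SD over libraries of both sexes. Where all libraries of a group had 0 counts, a fold is given as a lower bound against 3 counts per library, which covers counting error only.

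Genes to be named were chosen by a rule fixed before the data were examined. In each contrast these were up to 8 called genes per direction with the largest change, the same sign in each sex (or, for the sex contrast, in each strain), a mean of at least 1 CPM and a symbol that is not a predicted or clone-based name, and for strain differences the 4 of smallest adjusted p per direction. Up to 4 members of smallest adjusted p were added from each gene list, and Xist, the Y-linked genes, Nnt, Pdk4, Angptl4, Ucp3, Nppa, Nppb, Myh7 and the core clock genes were always included. That the core clock genes are Arntl, Clock, Per1, Per2, Cry1, Cry2 and Nr1d1 was decided after the data were seen. Some genes that the rule selects are not reported here. The fixed genes are given for the diet, strain and sex contrasts and not for each interaction.

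The 40 gene lists were also fixed beforehand. Of these, 24 cover PPAR-responsive lipid genes, mitochondrial beta-oxidation, glucose uptake and glycolysis, ketone body use, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, cholesterol synthesis, fatty acid synthesis, the circadian clock, cardiac stress, calcium handling, extracellular matrix, interferon response, antigen presentation, inflammatory cytokines, FoxO and glucocorticoid targets, insulin signalling, the integrated stress response, heat shock, NRF2 targets, immediate early genes, the cell cycle, Y-linked genes and X-inactivation and escape genes. The other 16 hold markers of cardiomyocytes, atrial cardiomyocytes, endothelial cells, fibroblasts, smooth muscle and pericytes, macrophages, T and NK cells, B and plasma cells, neutrophils and monocytes, erythroid cells, white and brown adipocytes, mesothelial cells, skeletal muscle, Schwann and nerve cells, and thymus and lung epithelium. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, and adjusted over the 40 lists of a contrast. With the estimated correlation 2 lists were called in the sex difference, the Y-linked and the X-inactivation and escape genes, and 0 lists in each of the other 15 contrasts. At the preset correlation between 2 and 15 lists were called per contrast. Counts of called members are given over all genes tested and adjusted over the list alone.

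Simulated counts with the means and library sizes of the real data and 200 changed genes, drawn from those with a mean of at least 1 CPM, were analysed first. In the simulated diet effect over 17203 genes, edgeR recovered 72 of 100 genes changed 1.5-fold and 92 of 100 changed 2-fold, and 11 of its 175 calls (6.29%) were false. The false share was 4.84% (9 of 186 calls) in the simulated strain difference and 1.06% (2 of 188) in the simulated sex difference. For DESeq2 1.42.0 it was 11.2% (22 of 197), 8.59% (17 of 198) and 8.25% (17 of 206), and for limma-voom 4.79% (8 of 167), 4.89% (9 of 184) and 3.12% (6 of 192). The check on simulated data had first been set to stop for each tool and was relaxed to edgeR alone after DESeq2 exceeded it, so counts by DESeq2 are alternatives only. A simulated list of 20 genes changed 1.5-fold was called with both correlations, and 0 of 50 unchanged lists were called. Genes were simulated independently of each other. The simulation therefore cannot tell how often the preset correlation calls lists falsely in the real data, where genes may be correlated.

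The library identifiers in the labels fall into 3 ranges, here called the first, the second and the third, which the labels do not describe as batches. Female C57BL/6J libraries came from the first and the third range in both diets and male ones from the first and second. In CAST/EiJ the 10% fat libraries came from the first and second range and the 44% fat libraries from the first and the third. In NZO/HlLtJ, females at 10% fat and males at 44% fat came from the second range and the other groups from the third. The difference of the diet effect between the sexes of this strain therefore cannot be told apart from the range. The same difference over all strains includes this part. Alternatives fixed beforehand were RLE factors, DESeq2, limma-voom, no filter, a stricter filter of 1 CPM in at least 12 libraries, the identifier range as a block, limma on the deposited log2-scale values, the libraries of one strain alone, the first identifier range alone, a threshold of 1 on the absolute log2 fold change, and leaving out each library in turn. Added after the data were seen were leaving out 3 libraries together that stood apart on marker genes or a principal component, and leaving out mitochondrially encoded genes and the ribosomal RNA-like gene Rn18s-rs5. Near-identical transcripts of ribosomal protein genes and mt-Co2 were found with minimap2 2.31-r1302 at 95% identity over 50% of the shorter transcript. Copies of other genes were not searched, so a gene named below without a mark may have near-identical copies too.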

Results

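RNA of mouse heart was sequenced in 24 libraries to ask how the response to a diet high in fat and sugar differs between genetic backgrounds that serve as models of type 2 diabetes. C57BL/6J is a common laboratory strain, CAST/EiJ is an inbred strain derived from wild Mus musculus castaneus, and NZO/HlLtJ is a polygenic strain that becomes obese and, in males above all, diabetic. Each of the 12 groups of strain, sex and diet (labelled 10% or 44% fat, each with fiber) held 2 libraries, so each diet effect compared 4 libraries with 4 and each strain difference 8 with 8. Total counts per library lay between 30205073 and 52254058. Of 20961 listed genes, 17203 entered the tests. Mitochondrially encoded genes took 20.2% to 28.8% of the counts of a library and ribosomal RNA-like sequence 1.03% to 4.35%. The biological coefficient of variation was 0.127.

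Sex-linked genes followed the labels in the 24 libraries. Xist, the RNA that silences one X chromosome, lay between 312 and 509 CPM in females and between 0.19 and 2.23 CPM in males. Eif2s3y lay between 39.4 and 57.3 CPM in males and had 1 count in all female libraries together. Kdm5d lay between 17.4 and 23.8 CPM in males with 2 counts in females. Nnt, which encodes the mitochondrial transhydrogenase and carries a deletion in C57BL/6J animals, was counted over the whole gene at 435 ± 21.4 CPM in C57BL/6J (SD, n = 8), against 721 ± 82.9 CPM in CAST/EiJ and 514 ± 23.2 CPM in NZO/HlLtJ. A count over the whole gene does not bear on the deletion or on the strain label. The first principal component of 12842 genes held 60.1% of the variance and the second 17.3%. Replicate libraries of each group differed by more than sampling noise in each of the 12 groups (chi-square per degree of freedom 10.8 to 63.2), so none was a repeated deposit.

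In C57BL/6J hearts the diet high in fat raised 2 genes of mitochondrial fatty acid oxidation, Acaa2 and Hadh, of 18 listed. Acaa2 (ENSMUSG00000036880, chromosome 18, 74779197 to 74806207), the thiolase that closes each round of beta-oxidation, rose from 534 ± 55 to 665 ± 49.5 CPM (SD, n = 4; log2 change 0.32, SE 0.05, adjusted p = 0.0289). Hadh (ENSMUSG00000027984, chromosome 3, 131233419 to 131272101), the hydroxyacyl-CoA dehydrogenase of the step before, rose from 416 ± 39.3 to 510 ± 17.5 CPM (0.30, SE 0.05, adjusted p = 0.0432). The largest change was that of Igsf1 (ENSMUSG00000031111, X chromosome, 49782536 to 49797749), which encodes a membrane glycoprotein of the immunoglobulin superfamily and rose from 12.4 ± 3.09 to 19.7 ± 3.27 CPM (0.68, SE 0.07, adjusted p = 0.000472). Hopx, a cardiac homeodomain cofactor whose antisense partner Hopxos makes its count uncertain, rose from 118 ± 3.21 to 149 ± 7.1 CPM (adjusted p = 0.0432). Creg1, a secreted lysosomal glycoprotein, rose by 0.30 (adjusted p = 0.0289) and the membrane protein gene Stom by 0.29 (adjusted p = 0.0336). Sorl1, a sorting receptor, was the 1 gene that fell, from 24.3 ± 2.17 to 18.9 ± 1.09 CPM (log2 change -0.36, SE 0.06, adjusted p = 0.0289).

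These 7 genes, 6 higher and 1 lower, were those called by edgeR, with 966 genes at an unadjusted p under 0.05. DESeq2 called 39, limma-voom 6, and a fit of the 8 C57BL/6J libraries alone 36. With the identifier range as a block the calls of Hadh (0.30, adjusted p = 0.0646) and Hopx (0.33, adjusted p = 0.0875) were lost, at the same fold changes as without it. Within the first identifier range, with 1 library per group, 2 genes were called, neither of them among the 7. The count was 1 without either library of the females at 10% fat, either library of the males at 10% fat, the second of the females at 44% fat or the second of the males at 44% fat. It was 2 without the first library of either 44% fat group or either NZO/HlLtJ female at 10% fat, and 21 without either NZO/HlLtJ male at 44% fat. The call of Igsf1 was kept without each of the 24 libraries in turn. Those of Hopx and Hadh were lost without any 1 of 18 libraries, Stom of 12, Acaa2 and Sorl1 of 9 and Creg1 of 8.

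**Figure D1:**
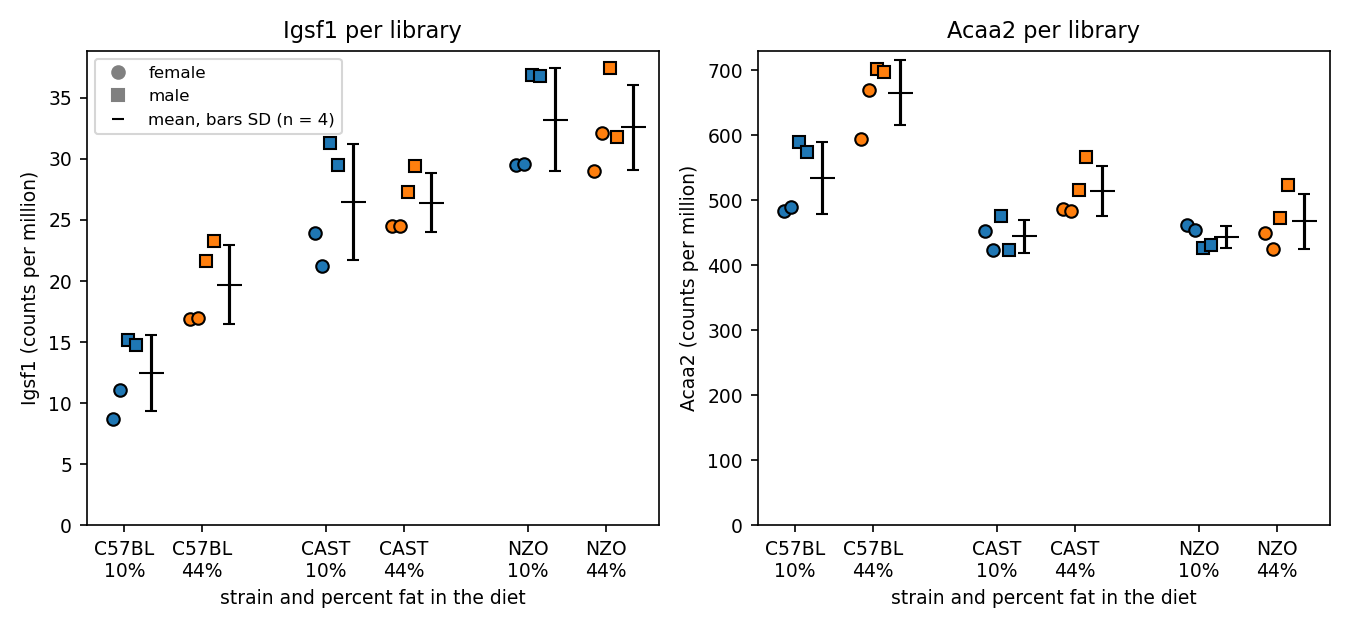
CPM of Igsf1 and Acaa2 (vertical axes) in each library by strain, sex and diet, with the mean and SD of the 4 libraries of each strain and diet. In C57BL/6J the means rose from 12.4 to 19.7 CPM for Igsf1 and from 534 to 665 CPM for Acaa2.

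As a group, all 18 measured genes of the beta-oxidation list had positive fold changes in C57BL/6J, with a median of 0.23. Of these, 2 were called over all genes and 15 when adjusted over the list alone. The positive sign was not particular to this strain. In CAST/EiJ and NZO/HlLtJ each listed gene but Etfb (0 and -0.08) had a positive fold change as well. In C57BL/6J Slc25a20, the carnitine-acylcarnitine carrier, had a log2 change of 0.37 (adjusted p = 0.166) and Hadha of the trifunctional protein 0.29 (adjusted p = 0.166). The list was called at the preset correlation (adjusted p = 2.83e-26) and not when the correlation was taken from the data (adjusted p = 0.188 with an estimated correlation). Fabp3, the fatty acid binding protein of heart, had a change of 0.29 (adjusted p = 0.281) within the PPAR-responsive list, of which 0 of 19 members were called over all genes and 1 over the list alone (median 0.12, adjusted p = 0.00445, and adjusted p = 0.882 with an estimated correlation). The 13 mitochondrially encoded subunits of oxidative phosphorylation all had positive changes (median 0.13, adjusted p = 3.53e-05; adjusted p = 0.554 with an estimated correlation), mt-Co3 having the smallest p at 0.17. Nuclear-encoded subunits had a median of 0.04 and NRF2 targets of 0.05, with adjusted p = 0.952 and adjusted p = 0.188 with an estimated correlation.

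The clock list had a median of 0.27 (adjusted p = 0.00445; adjusted p = 0.188 with an estimated correlation), and none of its 18 members was called by edgeR. Bhlhe40 stood at 0.47, Per1 at 0.68 and Per2 at 0.69, while Arntl stood at -0.30, Clock at 0.00, Cry1 at 0.09, Cry2 at 0.11 and Nr1d1 at 0.01, with adjusted p = 0.716 or more for each. Immune markers lay lower: the median was -0.13 for macrophages, -0.12 for antigen presentation, -0.64 for T and NK cells and -0.96 for B and plasma cells (adjusted p = 0.00935, 0.00796, 0.00454 and 0.00445), and with an estimated correlation adjusted p = 0.554 for the T and NK cell list and 0.882 for the others. The first male library at 10% fat lay apart in its B and plasma cell marker score (2.16), and Ighm, the IgM heavy chain gene, had 14.2 ± 15 CPM at 10% fat and 6.06 ± 1.12 at 44%. The fasting-responsive genes Pdk4, Angptl4 and Ucp3 stood at -0.06, -0.35 and -0.09 and the cardiac load genes Nppa, Nppb and Myh7 at -0.10, -0.53 and -0.32, with adjusted p = 0.954 or more. Nnt stood at -0.03 and Xist at -0.08 (adjusted p = 0.995 and 0.999).

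In CAST/EiJ no gene was called for diet by edgeR (smallest adjusted p = 0.165; 1137 genes at an unadjusted p under 0.05), by limma-voom 0 and by DESeq2 29. The thioesterase genes of fatty acyl-CoA, Acot1 and Acot2, had log2 changes of 1.13 (SE 0.26, adjusted p = 0.347) and 0.45 (SE 0.16, adjusted p = 0.656), and Acaa2 of 0.21 (SE 0.05, adjusted p = 0.366). Adjusted over the list alone, 8 of 18 beta-oxidation genes were higher and 2 of 19 PPAR-responsive genes, with medians of 0.12 and 0.18 (adjusted p = 1.55e-09 and 7.97e-08; adjusted p = 0.395 with an estimated correlation for both). Within the first identifier range alone the beta-oxidation median was 0.06 and the list was not called (adjusted p = 0.133). Collagen and matrix genes were higher over the list alone in 8 of 26 cases (median 0.15, adjusted p = 2.01e-07; adjusted p = 0.395 with an estimated correlation), led by Col6a2 at 109 ± 14.7 against 90.6 ± 4.35 CPM. Endothelial markers such as Cldn5, a tight junction protein, were higher over the list alone in 4 of 10 (median 0.17, adjusted p = 6.2e-05; adjusted p = 0.395 with an estimated correlation). The first female library at 44% fat lay apart in its endothelial marker score (0.39, the nearest other 0.07).

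Lipid synthesis genes of CAST/EiJ were lower over the list alone in 5 of 16, with a median of -0.17 and a mean of -0.76 (adjusted p = 0.0045; adjusted p = 0.565 with an estimated correlation). Fasn stood at 61.2 ± 16.7 CPM at 44% fat and 506 ± 697 at 10%, and Scd1 at 90.6 ± 35.4 and 748 ± 1030. These high SDs came from the first male library at 10% fat, whose white adipocyte marker score lay 1.72 above the mean of the CAST/EiJ libraries. Cholesterol synthesis genes had a median of -0.2 (adjusted p = 5.35e-05; adjusted p = 0.395 with an estimated correlation), cell cycle genes such as Top2a 0.61 (adjusted p = 4.39e-05; adjusted p = 0.565) and immediate early genes such as Egr1 0.19 (adjusted p = 0.00595; adjusted p = 0.494). Nuclear-encoded oxidative phosphorylation stood at -0.05 (adjusted p = 6.2e-05; adjusted p = 0.668) and the mitochondrially encoded genes 0.1 (adjusted p = 0.00745; adjusted p = 0.646). The second value of each pair is that with an estimated correlation. Pdk4 stood at 0.60, Angptl4 at 1.01, Ucp3 at 0.44, Nppa at -0.27, Nppb at 0.10 and Myh7 at -0.18, the smallest being adjusted p = 0.905. Among the clock genes, Arntl stood at -0.18, Clock at -0.08, Per1 at 0.01, Per2 at 0.08, Cry1 at -0.01, Cry2 at 0.10 and Nr1d1 at -0.29. Nnt stood at 0.01, and adjusted p = 0.92 was the smallest among these 8 genes. In this strain diet is partly tied to the identifier range: 62 genes were called within the first range alone and 4 with the range as a block. The count was 18 without the second male library at 10% fat and 2 without either female library at 10% fat, the second female library at 44% fat or either NZO/HlLtJ male at 44% fat. It was 1 without the first library of either 44% fat group.

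In NZO/HlLtJ edgeR likewise called 0 genes for diet (smallest adjusted p = 0.21; 1233 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 12. Among matrix genes, Thbs1, which encodes thrombospondin, stood at 24.5 ± 4.46 against 17 ± 1.51 CPM (log2 change 0.52, SE 0.11, adjusted p = 0.311), and Postn, a matrix protein of activated fibroblasts, at 0.39 (adjusted p = 0.583). Over the list alone 4 of 26 matrix genes were higher (median 0.13, adjusted p = 7.44e-07; adjusted p = 0.384 with an estimated correlation), and cardiac stress genes such as Xirp2 and Gdf15 had a median of 0.28 (adjusted p = 0.000681; adjusted p = 0.384). Beta-oxidation genes were higher over the list alone in 9 of 18, led by Hadhb at 1620 ± 206 against 1390 ± 31 CPM (median 0.13, adjusted p = 5.08e-08; adjusted p = 0.384), and PPAR-responsive genes had a median of 0.16 (adjusted p = 0.000111; adjusted p = 0.384). Tnni3, cardiac troponin I, stood at 2060 ± 221 against 2330 ± 211 CPM. Over the list alone 3 of 17 calcium and contraction genes and 3 of 10 cardiomyocyte markers were lower (medians -0.09 and -0.09, adjusted p = 0.00148 and 0.00314; adjusted p = 0.384 for both). In each of these pairs the last value is that with an estimated correlation.

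Of the other lists in NZO/HlLtJ, all 37 nuclear-encoded oxidative phosphorylation genes had negative changes (median -0.06, adjusted p = 1.08e-06; adjusted p = 0.47 with an estimated correlation), and 2 of 25 glycolysis genes were lower over the list alone (median -0.04, adjusted p = 0.0088; adjusted p = 0.572). Interferon response genes such as Isg15 had a median of -0.26 (adjusted p = 0.000155; adjusted p = 0.384). Macrophage markers stood at -0.21 (adjusted p = 0.000182; adjusted p = 0.384) and skeletal muscle markers at -0.69 (adjusted p = 0.0139; adjusted p = 0.384). The first female library at 10% fat lay apart in its skeletal muscle marker score (1.13, the nearest other 0.13). FoxO and glucocorticoid targets stood at 0.18 (adjusted p = 0.022; adjusted p = 0.725) and the integrated stress response at 0.1 (adjusted p = 0.0377; adjusted p = 0.384). In the same way, immediate early genes stood at 0.27 (adjusted p = 0.00122; adjusted p = 0.384) and fibroblast markers at 0.09 (adjusted p = 0.0428; adjusted p = 0.496). The second value of each pair again uses the estimated correlation. Pdk4 stood at 0.39, Angptl4 at 0.55, Ucp3 at 0.22, Nppa at -0.29, Nppb at 0.43, Myh7 at 0.56 and Nnt at 0.01, none under adjusted p = 0.739. The clock genes Arntl, Clock, Per1, Per2, Cry1, Cry2 and Nr1d1 stood at -0.25, 0.04, 0.57, 0.36, 0.04, -0.04 and -0.08, the smallest being adjusted p = 0.819. The first male library at 44% fat decided the count: without it 113 genes were called. Just 1 gene was called without the other male library at 44% fat or either female library at 10% fat.

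**Figure D2:**
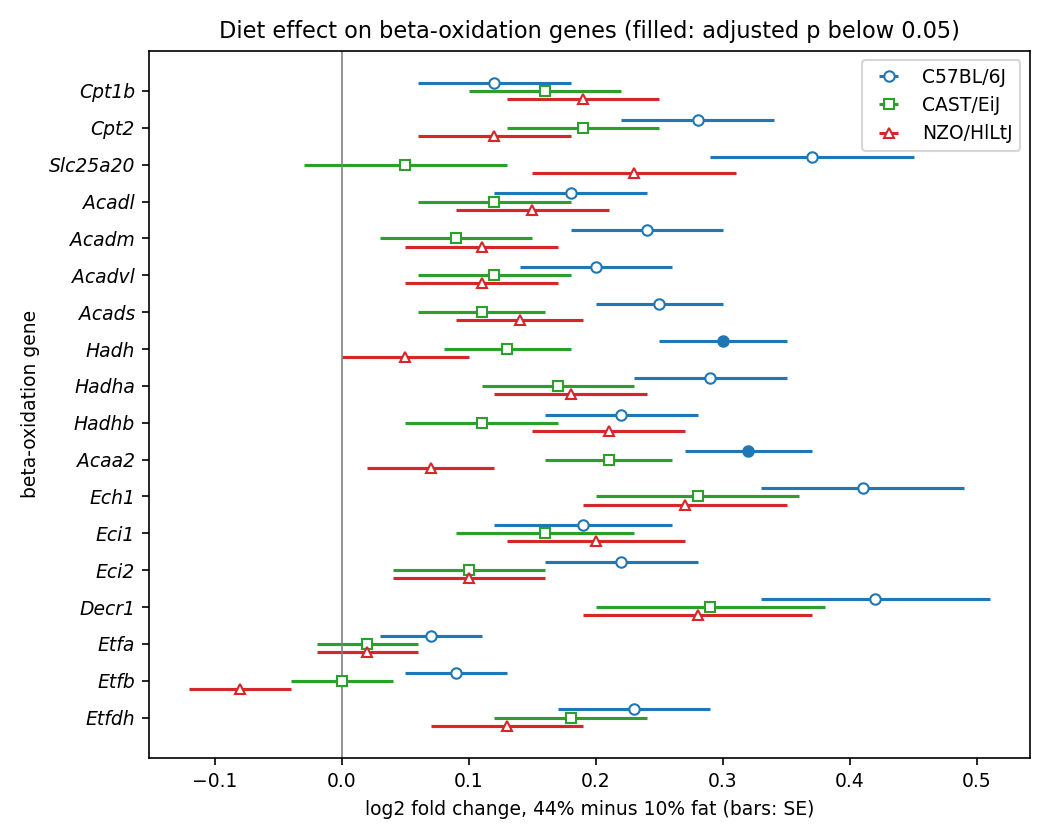
Log2 fold change, 44% over 10% fat, of the 18 beta-oxidation genes (horizontal axis) in each strain, with bars of 1 SE and filled points for called genes. All 18 points lie above 0 in C57BL/6J, where Acaa2 and Hadh were called. In the other strains each gene but Etfb (0 in CAST/EiJ, -0.08 in NZO/HlLtJ) lies above 0 as well.

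The design's central question, whether strains respond differently to diet, was tested as the difference between their diet effects. Igsf1 was the 1 gene called, its diet effect being lower in NZO/HlLtJ than in C57BL/6J (difference -0.70, SE 0.10, adjusted p = 0.0323). edgeR gave 818 genes at an unadjusted p under 0.05 in this contrast, and DESeq2 called 4 and limma-voom 0. The call was lost without any 1 of 17 libraries: all of C57BL/6J but the second female at 10% fat, the 4 of CAST/EiJ at 44% fat, the second CAST/EiJ male at 10% fat, the 4 of NZO/HlLtJ at 10% fat and the first NZO/HlLtJ female at 44% fat. By contrast, 3 genes were called without the second NZO/HlLtJ male at 44% fat and 2 without the second female at 44% fat. For CAST/EiJ against C57BL/6J edgeR called 0 genes (smallest adjusted p = 0.0576; 1123 at an unadjusted p under 0.05), DESeq2 8 and limma-voom 0. For NZO/HlLtJ against CAST/EiJ these counts were 0 (smallest adjusted p = 0.42; 799), 3 and 0. Other settings, given below, called some genes in these 2 contrasts. Among them were the identifier range as a block for CAST/EiJ against C57BL/6J, and leaving out each library in turn for both.

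Gene lists differed in their diet effects as follows at the preset correlation. Beta-oxidation genes responded less in NZO/HlLtJ and in CAST/EiJ than in C57BL/6J (median difference -0.12 in both, adjusted p = 0.000143 and 0.000708; adjusted p = 0.687 and 0.636 with an estimated correlation). Matrix genes responded more in both (0.17 and 0.24, adjusted p = 2.62e-07 and 1.73e-06; adjusted p = 0.595 and 0.636), as did cardiac stress genes in NZO/HlLtJ (0.45, adjusted p = 5.24e-05; adjusted p = 0.595). Across 17203 genes the diet effects had a Pearson correlation of 0.04 between NZO/HlLtJ and C57BL/6J (Spearman 0.128), -0.048 between CAST/EiJ and C57BL/6J (Spearman -0.011) and 0.079 between NZO/HlLtJ and CAST/EiJ (Spearman 0.092). Over the 13046 genes at 1 CPM or more, the Pearson correlations were 0.175, -0.137 and 0.088 in the same order (Spearman 0.192, -0.025 and 0.139). These correlations run across genes, which are not independent replicates, and these strains share no library.

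Strain differences far exceeded diet effects. Between NZO/HlLtJ and C57BL/6J hearts, 6108 genes differed, 3085 higher and 3023 lower in NZO/HlLtJ. Of these, 1215 had an absolute log2 fold change of at least 1, 625 higher and 590 lower. The skeletal alpha-actin gene Acta1 (chromosome 8, 123891767 to 123894736), which fetal and overloaded hearts express, stood at 1780 ± 706 CPM in NZO/HlLtJ and 157 ± 52.4 in C57BL/6J (log2 fold change 3.51, SE 0.25, adjusted p = 2.04e-07). Ankrd1, a stretch-responsive ankyrin repeat protein, stood at 1290 ± 265 against 515 ± 85.4 CPM (1.31, SE 0.12), and 5 of 12 cardiac stress genes were higher and 0 lower (median 0.3, adjusted p = 0.0378; adjusted p = 0.914 with an estimated correlation). Nppa, Nppb and Myh7, the usual load markers, were not called by edgeR (0.32, -0.59 and 0.18; adjusted p = 0.353, 0.0505 and 0.58). Nppb was called by DESeq2 (adjusted p = 0.022) and limma-voom (adjusted p = 0.0186). Of 26 matrix genes 17 were higher and 1 lower (median 0.37, adjusted p = 3.27e-07; adjusted p = 0.653 with an estimated correlation), among them Col1a1 at 235 ± 22.4 against 141 ± 9.36 CPM (0.74), Col5a1 (0.67) and Col1a2 (0.68). Fibroblast markers moved with them, 9 of 10 higher, Lum at 0.81 (median 0.47, adjusted p = 2.12e-05; adjusted p = 0.343 with an estimated correlation).

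Genes of antigen presentation were lower in NZO/HlLtJ in 14 of 16 cases and higher in 0 (median -0.77, adjusted p = 1.14e-08; adjusted p = 0.343 with an estimated correlation). The class I gene H2-K1 (chromosome 17, 33996017 to 34000333) stood at 30.9 ± 3.55 against 107 ± 8.37 CPM (log2 fold change -1.79, SE 0.07). The class II gene H2-Ab1 stood at 4.37 ± 1.41 against 20.1 ± 2.44 CPM, and the invariant chain gene Cd74 on chromosome 18 at 20.4 ± 4.84 against 58.7 ± 7 CPM (-1.53). Reads of NZO/HlLtJ alleles that differ from the reference could also be lost, above all in the H2 region, which was not tested. The 4 list members outside chromosome 17 had a median of -0.93, which does not show whether reads were lost at the members on it. Interferon response genes were lower in 16 of 20 and higher in 2 (median -0.53, adjusted p = 0.00265; adjusted p = 0.914 with an estimated correlation), Mx1, an antiviral GTPase, being higher at 5.12 ± 1.52 against 0.784 ± 0.346 CPM (2.74). Mitochondrially encoded subunits were lower in 10 of 13 (median -0.27, adjusted p = 1.18e-05; adjusted p = 0.653 with an estimated correlation), mt-Nd1 by -0.62, and nuclear-encoded ones lower in 16 and higher in 2 of 37 (median -0.07, adjusted p = 0.0116; adjusted p = 0.914). Of the mitochondrially encoded genes, near-identical copies were searched for mt-Co2 alone, so counts of the others may be divided between copies. Acaa2 was lower at 455 ± 32.1 against 600 ± 85.3 CPM, with 7 of 18 beta-oxidation genes lower and 2 higher. Other lists were not called. Glycolysis genes were higher in 10 and lower in 6 of 25, with the platelet phosphofructokinase Pfkp at 176 ± 20.5 against 53.2 ± 3.52 CPM. Insulin and growth signalling genes were higher in 2 and lower in 5 of 16, ketone body use higher in 1 and lower in 2 of 5. Inflammatory cytokines were higher in 3 and lower in 0 of 17 and Schwann and nerve cell markers higher in 4 and lower in 0 of 6, among them Cdh19.

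Single genes separated NZO/HlLtJ from C57BL/6J by far more. Cyfip2 (chromosome 11), a regulator of actin assembly, stood at 15.2 ± 1.66 against 250 ± 14.7 CPM (log2 fold change -4.05, SE 0.07, adjusted p = 4.19e-17) and Pdk1, a kinase that inhibits pyruvate dehydrogenase, at 45.1 ± 4.31 against 209 ± 13.6 CPM (-2.22). Tnni3k, a cardiac kinase that binds troponin I, was lower (-1.69) as was Tceanc2 (-4.04), while Sorl1 (1.92), Wdfy1 (2.34) and Iqgap2 (2.63) were higher, each with SE of at most 0.08. Mrap2, an accessory protein of melanocortin receptors, stood at 8.19 ± 3.18 against 0.0177 ± 0.0502 CPM and Ppp1r1c at 7.59 ± 1.32 against 0.0409 ± 0.0254. Lower near the floor were Lmntd1, Pydc4, Mndal, Zfp607, Slc6a17, Apol10b, Apol11b and Eps8l1, at 0.00319 to 0.215 CPM in NZO/HlLtJ and 2.14 to 17.8 CPM in C57BL/6J. Genes with near-identical copies are uncertain here: Pgk1-rs7 (12.51), Hamp2 (11.93), Tpm3-rs7 (7.87), the globin gene Hba-a1 (8.34), and the histone gene Hist2h2aa2, at least 96.6-fold higher. Of the fixed genes, Nnt (0.24, adjusted p = 0.000213) and Cry2 (0.30, adjusted p = 0.00415) were higher and the clock repressor Ciart was at 0.93 (adjusted p = 4.11e-05). Pdk4 (-0.20), Angptl4 (-0.95), Ucp3 (-0.88), Arntl (-0.54), Clock (-0.16), Per1 (0.69), Per2 (0.81), Cry1 (0.17) and Nr1d1 (-0.06) were not called by edgeR. Of these, limma-voom called Ucp3 (adjusted p = 0.0123), Angptl4 (adjusted p = 0.0296) and Arntl (adjusted p = 0.0497), and DESeq2 called Ucp3 (adjusted p = 0.0397).

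Between CAST/EiJ and C57BL/6J hearts 10116 genes differed, 5003 higher and 5113 lower in CAST/EiJ. Of these, 2805 had an absolute log2 fold change of at least 1, 1137 higher and 1668 lower. Reads of CAST/EiJ may align less well to the reference, which could lower counts or leave 0 counts in this strain. That possibility was examined below for antigen presentation genes alone, without deciding it. The beta-myosin heavy chain gene Myh7 (chromosome 14, 54970688 to 54994634), the slow isoform that in adult mouse ventricle gives way to Myh6 and that the antisense Mhrt overlaps, stood at 960 ± 216 CPM in CAST/EiJ and 150 ± 67.2 in C57BL/6J (log2 fold change 2.69, SE 0.23, adjusted p = 4.6e-07). Ryr2, the calcium release channel, was higher at 4920 ± 390 against 3250 ± 113 CPM and Mybpc3, myosin-binding protein C, lower at 1730 ± 146 against 3050 ± 305 CPM. In all 6 of 17 calcium and contraction genes were higher and 6 lower, and 4 of 12 cardiac stress genes higher and 3 lower. Fatty acid oxidation lay lower: 16 of 18 genes of the list were lower and 1 higher (median -0.24, adjusted p = 0.000494; adjusted p = 0.994 with an estimated correlation), with the medium-chain dehydrogenase Acadm at 562 ± 47.2 against 950 ± 98.9 CPM (-0.75, SE 0.04). Pdk4 (-1.62, adjusted p = 0.00566) and the uncoupling protein gene Ucp3 (-1.41, adjusted p = 0.00449) were also lower, and Ucp2 was higher at 184 ± 33.7 against 77.7 ± 15.2 CPM, while 10 of 19 PPAR-responsive genes were lower and 2 higher without a call of the list (adjusted p = 0.213).

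Antigen presentation genes were lower in CAST/EiJ in 15 of 16 and higher in 0 (median -1.61, adjusted p = 2.38e-07; adjusted p = 0.717 with an estimated correlation). H2-D1 (chromosome 17, 35262730 to 35267499) stood at 31.2 ± 2.84 against 122 ± 9.43 CPM, beta-2 microglobulin B2m at 59.8 ± 5.5 against 147 ± 15.9 CPM and Nlrc5, the activator of class I genes, at 0.9 ± 0.251 against 6.34 ± 1.37 CPM. Interferon response genes were lower in 16 of 20 and higher in 2 (median -1.85, adjusted p = 7.61e-06; adjusted p = 0.884 with an estimated correlation), Irf7, a master factor of type I interferon, by -3.33 (SE 0.16) and Ifi44 by -5.96 (SE 0.24). The immunity-related GTPase gene Iigp1 had 0 counts in CAST/EiJ and was at least 465-fold lower than in C57BL/6J, and Tgtp2 stood at 0.00684 ± 0.013 against 16.1 ± 2.89 CPM. T and NK cell markers were lower in 7 of 10, though under 1 CPM in both strains (Gzma 0.0513 ± 0.0409 against 0.353 ± 0.121 CPM; list median -1.75, adjusted p = 0.119). Macrophage markers were lower in 4 and higher in 1 of 10 (median -0.08, adjusted p = 0.716).

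**Figure D3:**
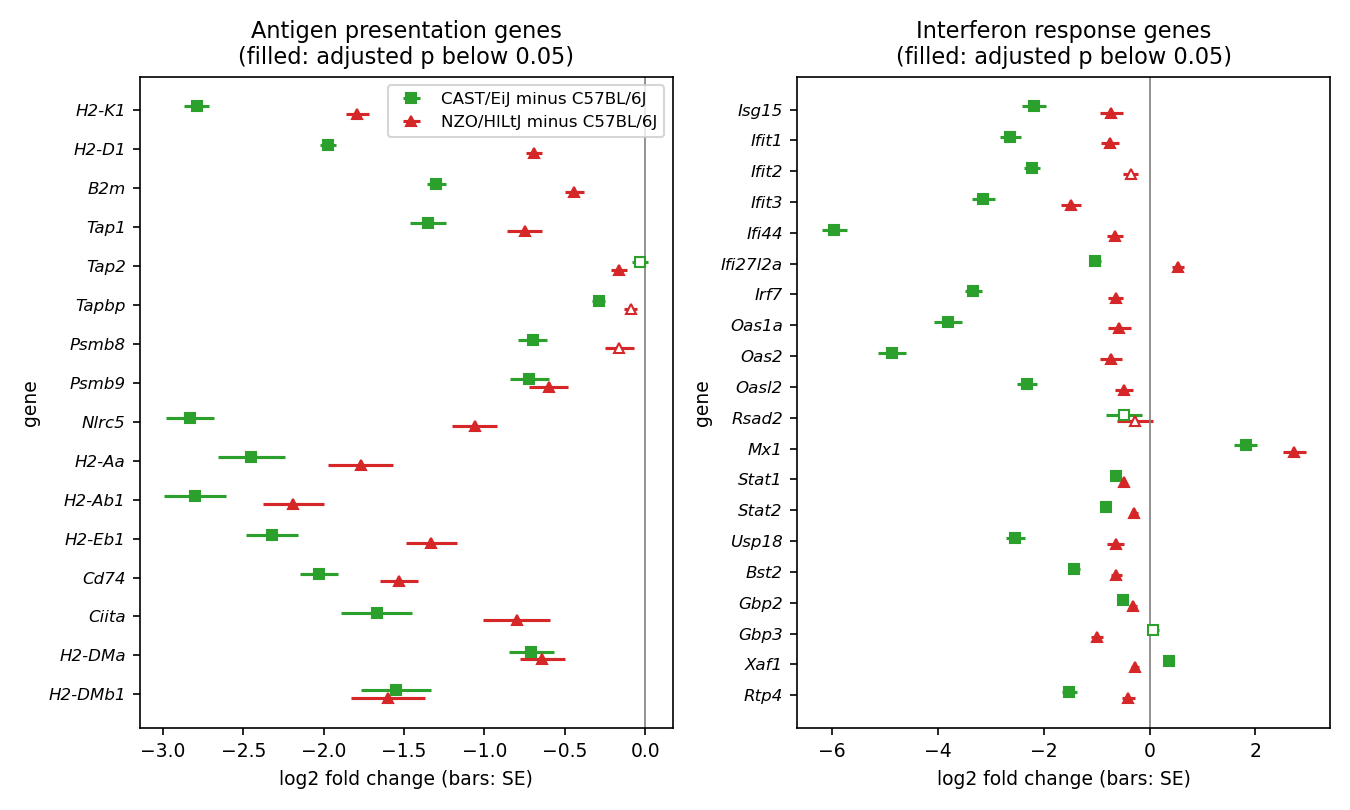
Log2 fold change against C57BL/6J, with bars of 1 SE, of the genes of the antigen presentation and interferon response lists in CAST/EiJ and NZO/HlLtJ. The medians of antigen presentation genes lie at -1.61 in CAST/EiJ and -0.77 in NZO/HlLtJ.

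Of the mitochondrially encoded genes 9 of 13 were lower in CAST/EiJ and 1 higher (median -0.45, adjusted p = 0.00395; adjusted p = 0.99 with an estimated correlation). Among these genes, near-identical copies were searched for mt-Co2 alone, so other counts may be divided as well. mt-Co2 stood at 22.1 ± 3.46 against 7770 ± 1090 CPM, but its near-identical nuclear copy Gm13341 stood at 3670 against 0.365 CPM. A further near-identical copy, Gm28661, held more counts than mt-Co2 and was lower in CAST/EiJ, at 13600 against 18500 CPM. The count of mt-Co2 is therefore uncertain. The same holds for ribosomal protein genes. Rpl27 had 75.8 ± 4.24 CPM in CAST/EiJ and 7.57 ± 0.805 in C57BL/6J, and its copy Rpl27-ps3 had 0.224 and 75.2 CPM. With 3 further copies they sum to 76 and 82.8 CPM.

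**Figure D4:**
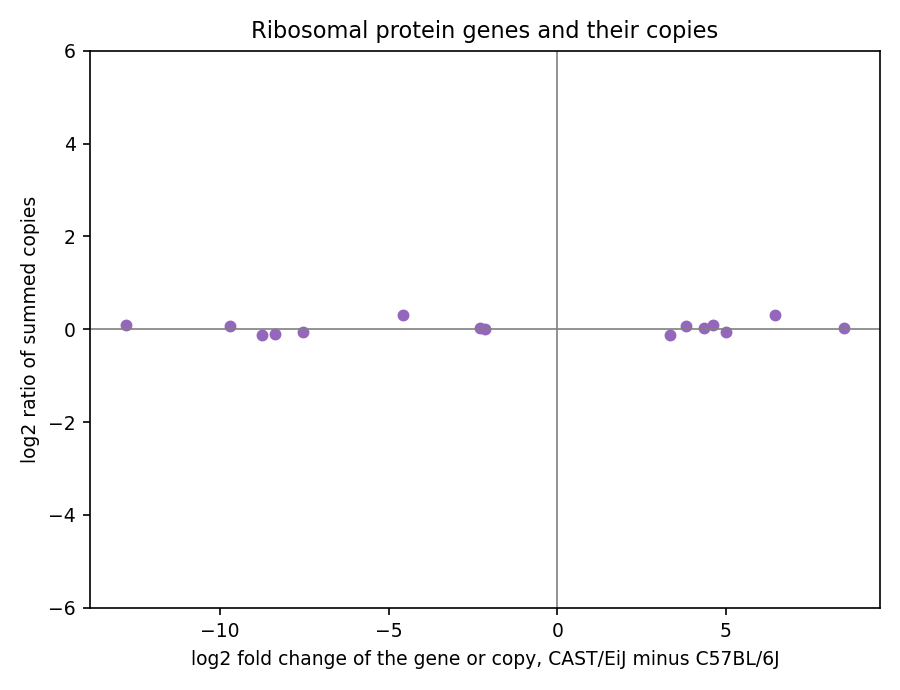
Log2 ratio of the summed copies of each ribosomal protein family (vertical axis) against the log2 fold change of the single gene (horizontal axis), CAST/EiJ over C57BL/6J. Drawn are genes that differ at least 4-fold and have a near-identical copy. Of the 16 genes that differ so, 7 were higher and 9 lower. Rps4l, without a copy and with a log2 ratio of -2.51, is not drawn. The 9 families drawn lie within 1 of 0 on the vertical axis.

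Several clock genes differed as well. Ciart, a transcriptional repressor of the clock, stood at 6.49 ± 2.41 CPM in CAST/EiJ against 1.55 ± 0.506 in C57BL/6J (log2 fold change 2.02, adjusted p = 3.25e-10). Per2 stood at 39.3 ± 33.1 against 9.38 ± 3.8 CPM (2.02, adjusted p = 0.00056), Cry2 at 0.22 (adjusted p = 0.0171), Arntl at -0.93 (adjusted p = 0.00887) and Clock at -0.19 (adjusted p = 0.0328). Of the 18 listed genes 9 were higher and 3 lower. Per1, Cry1 and Nr1d1 were not called (0.57, 0.35 and 0.25). The call of Clock was lost without any 1 of 8 libraries and that of Cry2 without 1. Heat shock genes were higher in 10 and lower in 0 of 18 (median 0.21, adjusted p = 0.192), Hspa1a, an inducible Hsp70, at 72.1 ± 46.1 against 9.13 ± 5.78 CPM. Integrated stress response genes were higher in 9 and lower in 1 of 16. NRF2 targets were higher in 8 and lower in 2 of 18, the quinone reductase Nqo1 lower at 17.3 ± 1.83 against 31.2 ± 2.45 CPM. Cholesterol synthesis genes were lower in 9 and higher in 3 of 21, nuclear-encoded oxidative phosphorylation higher in 14 and lower in 4 of 37, glycolysis higher in 13 and lower in 5 of 25, and matrix genes higher in 10 and lower in 3 of 26. Fibroblast markers were lower in 5 and higher in 1 of 10, Pi16 at 19.4 ± 3.21 against 50.9 ± 6.67 CPM. None of the lists from heat shock to fibroblast markers was called.

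Further marker lists in CAST/EiJ against C57BL/6J, none called, had these members higher and lower. They were smooth muscle and pericytes 4 and 3 of 10, cardiomyocytes 3 and 3 of 10, atrial cardiomyocytes 0 and 2 of 8, and endothelial cells 4 and 0 of 10. Blood and fat cell lists were neutrophils and monocytes 4 and 1 of 7, erythroid cells 3 and 0 of 8, B and plasma cells 0 and 0 of 8 (median 0.08), white adipocytes 1 and 0 of 10, and brown adipocytes 0 and 1 of 8. The others were mesothelial and epicardial cells 0 and 0 of 8, Schwann and nerve cells 1 and 5 of 6, and thymus and lung epithelium 0 and 1 of 2. Among the largest single differences, Cyfip2 stood at 1.9 ± 0.478 against 250 ± 14.7 CPM (log2 fold change -7.06). The paraoxonase Pon2 stood at 3.32 ± 0.393 against 33 ± 1.28 CPM (-3.31) and the X-linked noncoding RNA Firre at -2.89. Fam213b, which overlaps Mmel1 on the other strand and is uncertain for that reason, had 0 counts in CAST/EiJ and was at least 606-fold lower. Wfdc17 was lower at least 28-fold and Tmem254b, which has copies, at least 36.4-fold. Tas1r1 (8.20), Myo16 (8.16), Mrap2 (8.94), Snph (7.17), Ephb1 (3.85) and Ino80c (2.12) were higher as well. Lmntd1 was lower (-8.29). Pgk1-rs7 (12.96), Eno1b (10.90) and Amd2 (8.05) were higher but have near-identical relatives. Nnt was higher (0.73, adjusted p = 4.64e-11). Angptl4 (-0.91), Nppa (-0.26) and Nppb (-0.18) were not called.

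NZO/HlLtJ and CAST/EiJ differed in 10373 genes, 5248 higher and 5125 lower in NZO/HlLtJ. An absolute log2 fold change of at least 1 was found for 2918, 1724 higher and 1194 lower in NZO/HlLtJ. Reads of CAST/EiJ that align less well to the reference could add to the higher ones. Fibroblast genes were higher in NZO/HlLtJ in 9 of 10 cases (median 0.71, adjusted p = 0.00049; adjusted p = 0.787 with an estimated correlation), such as the proteoglycan gene Dcn at 460 ± 45.5 against 256 ± 20.4 CPM. Matrix genes were higher in 13 of 26 with 2 lower (median 0.24, adjusted p = 0.0333; adjusted p = 0.965), such as Postn at 68.2 ± 13.7 against 22.3 ± 3.3 CPM. Interferon response genes were higher in 16 and lower in 2 of 20 (median 1.52, adjusted p = 0.00049; adjusted p = 0.874). Antigen presentation genes were higher in 12 and lower in 1 of 16 (median 0.61, adjusted p = 0.00694; adjusted p = 0.885). T and NK cell markers were higher in 9 of 10 (median 2.15, adjusted p = 0.0241; adjusted p = 0.874), Gzma at 0.468 ± 0.193 against 0.0513 ± 0.0409 CPM. Heat shock genes were lower in 15 of 18 (median -0.36, adjusted p = 0.00566; adjusted p = 0.965). Nuclear-encoded oxidative phosphorylation was lower in 23 and higher in 4 of 37 (median -0.14, adjusted p = 0.00251; adjusted p = 0.965). In each pair the second value uses the estimated correlation. Beta-oxidation genes were higher in 13 and lower in 2 of 18 without a call of the list (adjusted p = 0.0513).

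Myh7 was lower in NZO/HlLtJ than in CAST/EiJ (182 ± 89 against 960 ± 216 CPM; log2 fold change -2.51, adjusted p = 7.98e-07), while Acta1 (2.83) and the muscle ankyrin gene Ankrd23 (1.38) were higher. Pdk1 was lower (-2.85), Pdk4 higher (1.42, adjusted p = 0.0116) and Per2 lower (-1.21, adjusted p = 0.0126). Pon2 (3.74) and Plac9b (5.84) were higher, and As3mt (-1.63), Tceanc2 (-3.87), Ephb1 (-3.93) and Nnt (-0.48) lower. Rps13, with near-identical copies, stood at 2.33. Iigp1 was at least 195-fold higher, Fam213b at least 579-fold, Hist2h2aa2 at least 109-fold, Tmem254b at least 41.3-fold, Wfdc17 at least 32.7-fold and the glutamate receptor gene Grin2c at least 28.4-fold, each with 0 counts in CAST/EiJ. Hamp2 (12.87) was higher too. Mx2 stood at 0.00333 ± 0.00941 against 6.59 ± 1.23 CPM. Nlrp1a (-9.53), Mndal (-7.64), Myo16 (-7.58), Tas1r1 (-8.02) and Eno1b (-10.41) were lower. Angptl4 (-0.05), Ucp3 (0.53), Nppa (0.59), Nppb (-0.41), Arntl (0.39), Clock (0.03), Per1 (0.12), Cry1 (-0.18), Cry2 (0.08) and Nr1d1 (-0.31) were not called by edgeR. Nppa was called by DESeq2 (adjusted p = 0.0307) and limma-voom (adjusted p = 0.0262).

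Between the sexes 64 genes differed, 34 higher and 30 lower in males. Beyond the Y-linked Eif2s3y and Kdm5d, males had higher complement C7 (chromosome 15, 4988762 to 5063773) at 10.8 ± 7.2 against 2.86 ± 1.68 CPM (SD, n = 12; log2 fold change 1.82, SE 0.15, adjusted p = 4.5e-06). Also higher were the opioid precursor gene Penk at 5.29 ± 2.18 against 2.29 ± 1.13 CPM (1.22), the aminopeptidase gene Lvrn (1.59), Lect1 (1.41) and the interferon-inducible Ifi205 (1.33). Females had higher levels of genes that escape X inactivation. Of the list, 5 of 5 were lower in males (median -0.79; adjusted p = 4.53e-07 with an estimated correlation), among them Eif2s3x at 102 ± 4.52 against 176 ± 7.23 CPM, Kdm6a (-0.88) and Kdm5c (-0.71), and X-linked Pbdc1 (-0.71). The 2 Y-linked genes had a list median of 12.7 (adjusted p = 1.39e-05 with an estimated correlation). Tsix (-2.18), which overlaps Xist (-8.95) on the other strand, is uncertain. Lum, a collagen-binding proteoglycan, was slightly lower in males (-0.27, adjusted p = 0.0255), as were Lrrc55 (-1.11) and Ifit1bl2 (-1.30), while Tpm3-rs7 (1.12), which has close relatives, was higher. The means lay closer together than these fitted changes for Tpm3-rs7 (8.4 ± 6.29 against 7.52 ± 5.74 CPM) and Ifit1bl2 (2.3 ± 1.77 against 2.91 ± 2.31 CPM). With limma-voom these 2 genes stood at 0.74 and -0.92 (adjusted p = 0.223 and 0.239). With the identifier range as a block the calls of Tpm3-rs7 (1.13, adjusted p = 0.0657), Ifit1bl2 (-1.24, adjusted p = 0.0794) and Lrrc55 (-1.11, adjusted p = 0.0647) were lost, at similar fold changes. edgeR gave 1539 genes at an unadjusted p under 0.05 and DESeq2 called 132. The count fell to 39 without the second NZO/HlLtJ female at 44% fat and to 42 without the first C57BL/6J male at 10% fat or the second NZO/HlLtJ male at 10% fat. The calls of Tpm3-rs7, Ifit1bl2, Lrrc55, Ifi205 and Lum were lost without any 1 of 21, 20, 17, 16 and 12 libraries.

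Interferon response genes were lower in males over the list alone in 11 of 20, with Isg15 at 1.61 ± 1.21 against 2.36 ± 1.43 CPM (list median -0.32, adjusted p = 2.41e-12; adjusted p = 0.106 with an estimated correlation). Beta-oxidation genes were higher over the list alone in 7 of 18 (median 0.08, adjusted p = 5.47e-09; adjusted p = 0.586), with Acaa2 at 0.11 (adjusted p = 0.133). Atrial markers such as Myl4 and Sln had a median of 0.43 (adjusted p = 3.72e-05; adjusted p = 0.586), cardiac stress genes 0.18 (adjusted p = 0.000606; adjusted p = 0.586), immediate early genes 0.09 (adjusted p = 0.0304; adjusted p = 0.89). Integrated stress response genes stood at 0.07 (adjusted p = 0.00333; adjusted p = 0.0668), nuclear-encoded oxidative phosphorylation 0.03 (adjusted p = 0.00127; adjusted p = 0.943) and heat shock genes -0.06 (adjusted p = 0.00165; adjusted p = 0.91). Again the second value uses the estimated correlation. The fixed genes Pdk4 (-0.22), Angptl4 (-0.07), Ucp3 (-0.40), Nppa (0.44), Nppb (0.42), Myh7 (0.19), Arntl (0.27), Clock (0.04), Per1 (0.12), Per2 (0.02), Cry1 (0.01), Cry2 (-0.07), Nr1d1 (-0.01) and Nnt (-0.09) were not called.

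No gene was called by edgeR for a difference of the sex effect between diets (784 at an unadjusted p under 0.05; 1 by DESeq2), between NZO/HlLtJ and C57BL/6J (796; 3 by DESeq2) or between CAST/EiJ and C57BL/6J (1023; 11 by DESeq2). Within strains the sex-by-diet contrast likewise called 0 genes in C57BL/6J (587; 0 by DESeq2), CAST/EiJ (957; 1) and NZO/HlLtJ (692; 0). Single libraries changed some of these counts. For CAST/EiJ against C57BL/6J, 27 genes were called without the first CAST/EiJ female at 10% fat, 3 without the second male at 10% fat. It was 2 and 1 without the first and second female at 44% fat. For sex by diet over all strains 1 gene was called without the first CAST/EiJ female of either diet. Within CAST/EiJ, 5 genes were called without the second male at 10% fat, 2 without the first female at 10% fat and 1 without either female at 44% fat. Within NZO/HlLtJ, 5 were called without the first male at 44% fat and 1 without the second or without the second female at 10% fat.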

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

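The measures searched for a library apart (marker scores, principal components, total count, mitochondrial and ribosomal RNA-like share) were chosen after PC4 and the marker scores had been seen. The predictions for ribosomal copies, the H2 region, macrophages and the cardiomyocyte share were written after those patterns had been seen, and the others before. Splits of the libraries numbered 50 at first and were reduced to 40 for run time after the first values had been seen.

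Of 69 measures by strain, 7 held a library far from the other 7 of its strain, where chance gives about 1 in 20. The first C57BL/6J male at 10% fat had a B and plasma cell marker score of 2.16. The second C57BL/6J male at 44% fat had 1.03% ribosomal RNA-like counts. The first CAST/EiJ female at 44% fat had an endothelial score of 0.39. In NZO/HlLtJ, the first male at 44% fat had a B and plasma cell score of 1.13 and a total of 52.3, in units of 1e6 counts, the second male at 44% fat lay at -29.6 on PC4, and the first female at 10% fat had a skeletal muscle score of 1.13.

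Igsf1 differed in its diet effect between NZO/HlLtJ and C57BL/6J by -0.70 (adjusted p = 0.0323). In 3 of 40 splits of the same libraries, the real one included, the number of genes called was as large (real 1, highest other 4). This met the prediction written beforehand for a number of calls that arises by chance. The lists that differed at the preset correlation and not with an estimated one were, for NZO/HlLtJ minus C57BL/6J, beta-oxidation (-0.12), glycolysis (-0.1), nuclear-encoded oxidative phosphorylation (-0.1), cardiac stress (0.45), calcium handling (-0.07), matrix (0.17), immediate early genes (0.24), T and NK cells (0.78) and B and plasma cells (1.31), the smallest being adjusted p = 0.595 with an estimated correlation. For CAST/EiJ minus C57BL/6J they were beta-oxidation (-0.12), nuclear-encoded oxidative phosphorylation (-0.08), cholesterol synthesis (-0.2), the clock (-0.23), matrix (0.24), antigen presentation (0.17), NRF2 targets (-0.09), the cell cycle (1.07), endothelial cells (0.18), macrophages (0.17) and B and plasma cells (0.85), the smallest being adjusted p = 0.186 with an estimated correlation. For NZO/HlLtJ minus CAST/EiJ they were the cell cycle (-0.82) and macrophages (-0.28), both adjusted p = 0.903 with an estimated correlation. The first C57BL/6J male at 10% fat, apart in its B and plasma cell score (2.16), is part of both B and plasma cell differences, and the first NZO/HlLtJ male at 44% fat (1.13) moves that of NZO/HlLtJ in the same direction. The first CAST/EiJ female at 44% fat (endothelial score 0.39) is part of the endothelial difference.

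Lists whose sex effect differed between diets, male minus female, were PPAR-responsive genes (0.17), beta-oxidation (0.09), glycolysis (-0.05), nuclear-encoded oxidative phosphorylation (0.05), interferon response (-0.39), FoxO targets (0.3), heat shock (0.16), the cell cycle (-0.44) and skeletal muscle (0.62), each adjusted p = 0.716 with an estimated correlation. Between NZO/HlLtJ and C57BL/6J the sex effect differed for beta-oxidation (-0.07), glycolysis (-0.13), nuclear-encoded oxidative phosphorylation (-0.11), cardiac stress (0.32), calcium handling (-0.06), matrix (0.18), cardiomyocytes (-0.08), atrial cardiomyocytes (-0.68) and fibroblasts (0.14), the smallest being adjusted p = 0.638 with an estimated correlation. Between CAST/EiJ and C57BL/6J it differed for the clock (-0.5), the cell cycle (-0.68) and smooth muscle and pericytes (-0.27), the smallest being adjusted p = 0.374 with an estimated correlation.

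Within C57BL/6J, sex-by-diet differences were those of interferon response (-0.63), B and plasma cells (-2.08) and erythroid cells (1.54), each adjusted p = 0.868 with an estimated correlation. The library with the B and plasma cell score of 2.16 is in this contrast too. Within CAST/EiJ they were those of beta-oxidation (0.13), nuclear-encoded oxidative phosphorylation (0.11), cholesterol synthesis (-0.24), fatty acid synthesis (-0.83), calcium handling (0.11), matrix (-0.4), interferon response (-0.61), antigen presentation (-0.21), heat shock (0.29), the cell cycle (-1.07), cardiomyocytes (0.16), endothelial cells (-0.25) and fibroblasts (-0.25), the smallest being adjusted p = 0.521 with an estimated correlation. The fatty acid synthesis value holds the first male at 10% fat, with a score of 1.35 for that list and 1.72 for white adipocytes, and the endothelial value the first female at 44% fat (0.39). Within NZO/HlLtJ, where this contrast cannot be told apart from the identifier range, they were those of PPAR-responsive genes (0.44), beta-oxidation (0.24), mitochondrially encoded genes (-0.16), fatty acid synthesis (0.32), matrix (0.22), FoxO targets (0.52), fibroblasts (0.28), T and NK cells (-1.12), neutrophils and monocytes (-1.27), erythroid cells (-0.96) and white adipocytes (2.17), the smallest being adjusted p = 0.536 with an estimated correlation. White adipocyte scores were 1.2 in the first male at 44% fat and -1.2 in the first male at 10% fat, which both move the value of 2.17 upward.

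Ribosomal protein genes that differed at least 4-fold between CAST/EiJ and C57BL/6J were weighed as reads shared between near-identical copies. Summed over copies, the median absolute log2 ratio was 0.08, against 4.8 for single genes, which is consistent with reads moving between copies. Rps4l, without a copy found, stayed at -2.51. For mt-Co2 the sum with its 2 copies had a log2 ratio of -0.61. Most of that sum was the copy Gm28661, at 13600 CPM in CAST/EiJ and 18500 in C57BL/6J. The prediction for mt-Co2 would have been met even without the counts of the other copy, Gm13341, so the sum cannot decide. No biological explanation was tested.

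Antigen presentation genes lower in CAST/EiJ were weighed against alleles of the H2 region that differ from the reference, a general loss of such reads, and fewer macrophages. The 4 members outside chromosome 17 had a median of -1.85, which does not show whether reads were lost at the members on it. Of 10000 random lists matched on expression, 0 percent had a median as low. These lists were not matched on how far genes differ from the reference, so they cannot exclude a loss of such reads here. Macrophage markers stood at -0.08. None of these 3 explanations fitted its prediction. No prediction was written for other immune cells. T and NK cell markers had a median of -1.75 and B and plasma cell markers of 0.08, neither list called (adjusted p = 0.119 and 0.943), so the cause is left open.

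Beta-oxidation genes higher at 44% fat in C57BL/6J were weighed against the identifier range and a larger share of cardiomyocyte RNA. Within the first range the list median was 0.22, and cardiomyocyte markers stood at -0.02, neither of which fitted those explanations. In C57BL/6J the diets were evenly spread over the ranges, so a shift between ranges could not have made this difference. The value within the first range therefore adds no support. Of 34 splits of the 8 libraries, 1, the real one, had a median as large (real 0.233, highest other 0.196). In CAST/EiJ 5 of 34 did (real 0.123, highest other 0.16) and in NZO/HlLtJ 7 of 34 (real 0.132, highest other 0.21).

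Splits were counted in simpler models of all 24 libraries, so their real counts can differ from those of the 12 group means. For diet within a strain, for strain and for sex, these models held no interactions of the factor that was split. For the interaction contrasts they held the interactions tested. Splits of the libraries of one strain gave as many called genes for diet in 1 of 34 in C57BL/6J (real 6, highest other 1), 34 of 34 in CAST/EiJ (real 0, highest other 50, the split by identifier range) and 34 of 34 in NZO/HlLtJ (real 0, highest other 3). The real one is counted in each. A real count of 0 makes each split as large by construction, so these comparisons hold no information in CAST/EiJ and NZO/HlLtJ. For strain, 1 of 40 splits was as large in NZO/HlLtJ minus C57BL/6J (real 6285, highest other 2927), in CAST/EiJ minus C57BL/6J (real 10150, highest other 0) and in NZO/HlLtJ minus CAST/EiJ (real 10378, highest other 7174), and for sex 1 of 40 (real 68, highest other 1). The strain splits mixed libraries of both strains in models without a term for the real strain. The strain difference then entered the spread or the label of each other split. The real split thus ranks first almost by construction, so the strain comparisons cannot decide whether chance made the counts. The other contrasts with a real count of 0 hold no information either, since 40 of 40 were as large by construction. Their highest other was 2 for diet by strain in CAST/EiJ minus C57BL/6J and 37 in NZO/HlLtJ minus CAST/EiJ. It was 2 for sex by diet, 1 for sex by strain in NZO/HlLtJ and 2 in CAST/EiJ.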

How the results depend on the processing

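The medians of 7 list results were followed: beta-oxidation for diet in each strain, antigen presentation in CAST/EiJ and in NZO/HlLtJ minus C57BL/6J, matrix in NZO/HlLtJ minus C57BL/6J and interferon response for sex. At the preset correlation they kept their direction and side of the threshold in 67 of 68 comparisons with another setting, and without each library in turn in 168 of 168. With an estimated correlation none of the 7 was called. Of named genes, 2431 values under other settings kept direction and side of the threshold, 35 reversed, 24 gained a call and 32 lost one. Causes were not tested unless given. Replicate numbers follow accession order. The labels name no pairs, and the identifier range, in which each C57BL/6J library has 1 of the other diet and the same sex, was fitted as a block. A library left alone in its group was assumed to vary like the other groups. With 4 libraries per side, the simulated diet effect left 28 of 100 changes of 1.5-fold uncalled, in genes with a mean of at least 1 CPM. Smaller changes, such as the 1.25-fold change of Acaa2 for diet in C57BL/6J, and genes of lower level were not simulated as changed.

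Counts of called genes moved by over 1.5 times as follows. With DESeq2 they were 39, 29 and 12 for diet in C57BL/6J, CAST/EiJ and NZO/HlLtJ (7, 0 and 0 with edgeR), 4, 8 and 3 for diet by strain in NZO/HlLtJ minus C57BL/6J, CAST/EiJ minus C57BL/6J and NZO/HlLtJ minus CAST/EiJ (1, 0 and 0). They were 132 for sex (64), 1 for sex by diet, 3 and 11 for sex by strain in NZO/HlLtJ and CAST/EiJ, and 1 for sex by diet in CAST/EiJ. With limma-voom diet by strain in NZO/HlLtJ minus C57BL/6J called 0. With RLE factors, and with abundant genes left out (chosen after seeing the data), diet by strain in CAST/EiJ minus C57BL/6J called 1. The identifier range as a block gave 4 for diet in CAST/EiJ and 4 for diet by strain in CAST/EiJ minus C57BL/6J. The deposited log2-scale values gave 4 for diet in CAST/EiJ, 2 in NZO/HlLtJ and 2 for diet by strain in NZO/HlLtJ minus C57BL/6J. C57BL/6J alone gave 36. The first identifier range alone, with fewer libraries, gave 2 in C57BL/6J and 62 in CAST/EiJ. Without 3 libraries together, chosen after seeing the data, diet in CAST/EiJ gave 2, sex 38 (14 higher and 24 lower) and sex by strain in NZO/HlLtJ 1. The diet calls in C57BL/6J split 6 higher and 0 lower with limma-voom and 4 and 2 with the block. At an absolute log2 fold change of at least 1, the strain counts were 1215, 2805 and 2918. With an estimated correlation 0 lists were called in each contrast but sex, with 2. The beta-oxidation median for diet in CAST/EiJ was 0.06 in the first range (adjusted p = 0.133). The Pearson correlation of diet effects between C57BL/6J and NZO/HlLtJ was 0.205 with the stricter filter and 0.191 with the deposited log2-scale values, against 0.04.

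Reversed values, none of them called, were these. For diet in C57BL/6J: Pdk4 0.03 with the block and 0.28 in the first range, and in the first range Angptl4 0.3, Ucp3 0.07, Nppa 0.15 and Nnt 0.01, and without the 3 libraries Myh7 0.15 and Cry1 -0.08. For diet in CAST/EiJ: Arntl 0.08 with the block and 0.22 in the first range, Cry1 0.1 with limma-voom, 0.29 with the block, 0.02 with the deposited log2-scale values and 0.24 in the first range, Per1 0 with DESeq2, -0.02 with the deposited values and -0.18 without the 3 libraries, and without these Per2 -0.15 and Nppb -0.03. For diet in NZO/HlLtJ, without the 3 libraries: Nnt -0.03, Clock -0.01, Cry1 -0.11, Cry2 0.03 and Nr1d1 0.03. For NZO/HlLtJ minus C57BL/6J: with the block Cry1 -0.06 and Nr1d1 0.16, and Nr1d1 0.12 without the 3 libraries. For NZO/HlLtJ minus CAST/EiJ: Per1 -0.23 with the block, and without the 3 libraries Per1 -0.06, Clock -0.02 and Angptl4 0.18. For sex: Angptl4 0.16 with limma-voom, 0.05 with the block and 0.07 with the deposited values and Cry1 -0.06 with the block.

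Of the diet effect in C57BL/6J, calls were lost for Hopx with limma-voom (adjusted p = 0.0676), the block (adjusted p = 0.0875) and without the 3 libraries (adjusted p = 0.114). They were lost for Hadh with the block (adjusted p = 0.0646) and without the 3 libraries (adjusted p = 0.0838), for Stom without them (adjusted p = 0.0958), for Sorl1 with limma-voom (adjusted p = 0.0995). For diet by strain, NZO/HlLtJ minus C57BL/6J, the call of Igsf1 was lost with limma-voom (adjusted p = 0.0659) and without the 3 libraries (adjusted p = 0.204). In the first range Igsf1 stood at 0.72 (adjusted p = 0.143). The other 6 of these genes lost their call there too, with fewer libraries. Their fold changes there were 0.32 for Hopx, 0.28 for Acaa2, 0.3 for Creg1, 0.32 for Hadh, 0.29 for Stom and -0.26 for Sorl1. In the sex difference, Tpm3-rs7, Ifit1bl2 and Lrrc55 lost their calls with limma-voom, the block, the deposited values and without the 3 libraries, Ifit1bl2 also with DESeq2 (adjusted p = 0.086) and Ifi205 without the 3 libraries (adjusted p = 0.13). Without them Pdk4 lost its call in NZO/HlLtJ minus CAST/EiJ (adjusted p = 0.0613) and Clock in CAST/EiJ minus C57BL/6J (adjusted p = 0.0824). Calls were gained by Nppb in NZO/HlLtJ minus C57BL/6J under 5 settings (adjusted p = 0.022 with DESeq2), where Ucp3 gained one with DESeq2, limma-voom and the deposited values (adjusted p = 0.0443) and Angptl4 and Arntl with limma-voom. Nppa gained one in NZO/HlLtJ minus CAST/EiJ with DESeq2 and limma-voom. Others were gained by Slc25a20 and Hadha for diet in C57BL/6J with DESeq2 (adjusted p = 0.00351 for both), by Acot1 (adjusted p = 0.00163) and Col6a2 (adjusted p = 0.0471) for diet in CAST/EiJ with DESeq2, by Acot1 (adjusted p = 0.00158) and Acot2 (adjusted p = 0.042) in the first range, and by Thbs1 for diet in NZO/HlLtJ with DESeq2 (adjusted p = 0.00801). For sex, Acaa2 gained one with DESeq2 (adjusted p = 0.0406) and Rtp4 (adjusted p = 0.0076) and Xaf1 (adjusted p = 0.0442) with the block. In C57BL/6J alone Slc25a20 (adjusted p = 0.0128) and Hadha (adjusted p = 0.00954) gained one as well.

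Without each library in turn, counts ranged from 1 to 21 for diet in C57BL/6J, 0 to 18 in CAST/EiJ and 0 to 113 in NZO/HlLtJ, 0 to 3, 0 to 8 and 0 to 4 for diet by strain, 39 to 79 for sex, 0 to 1 for sex by diet, 0 to 27 for sex by strain in CAST/EiJ, and 0 to 5 for sex by diet in CAST/EiJ and in NZO/HlLtJ. Fold changes of genes whose call or sign changed ranged as follows. For diet in C57BL/6J, Hopx 0.3 to 0.37, Acaa2 0.28 to 0.36, Creg1 0.28 to 0.32, Hadh 0.28 to 0.32, Stom 0.26 to 0.31, Sorl1 -0.41 to -0.31, Pdk4 -0.27 to 0.22, Angptl4 -0.66 to 0.21, Ucp3 -0.36 to 0.11, Nppa -0.38 to 0.36, Myh7 -0.63 to 0.15, Nnt -0.07 to 0.01, Slc25a20 0.31 to 0.42, Hadha 0.26 to 0.32, Clock -0.04 to 0.03, Cry1 -0.08 to 0.32 and Nr1d1 -0.17 to 0.26. For diet in CAST/EiJ, Nppb -0.19 to 0.31, Nnt -0.06 to 0.08, Acly -1.97 to -0.48, Arntl -0.77 to 0.14, Clock -0.19 to 0.06, Per1 -0.59 to 0.44, Per2 -0.46 to 0.87, Cry1 -0.29 to 0.46 and Cry2 0 to 0.19. For diet in NZO/HlLtJ, Ucp3 -0.18 to 1.21, Nnt -0.03 to 0.04, Hadhb 0.12 to 0.29, Decr1 0.14 to 0.4, Ech1 0.15 to 0.37, Cpt1b 0.11 to 0.27, Cd36 0.15 to 0.39, Fabp3 0.11 to 0.29, Clock -0.03 to 0.1, Cry1 -0.11 to 0.18, Cry2 -0.11 to 0.04 and Nr1d1 -0.22 to 0.03. For diet by strain, NZO/HlLtJ minus C57BL/6J, Igsf1 -0.79 to -0.62. For NZO/HlLtJ minus C57BL/6J, Angptl4 -1.86 to -0.67, Ucp3 -1.37 to -0.67, Nppb -0.7 to -0.46, Clock -0.2 to -0.13 and Nr1d1 -0.15 to 0.06. For CAST/EiJ minus C57BL/6J, Clock -0.26 to -0.13, Cry2 0.17 to 0.26, Per1 0.27 to 0.76, Cry1 0.11 to 0.49 and Nr1d1 0.07 to 0.37. For NZO/HlLtJ minus CAST/EiJ, Angptl4 -0.95 to 0.28, Ucp3 0.04 to 0.73, Nppa 0.43 to 0.71, Arntl 0.23 to 0.68, Clock -0.03 to 0.09, Per1 -0.04 to 0.41, Cry1 -0.32 to 0.05 and Nr1d1 -0.43 to -0.13. For sex, Ifi205 1.18 to 1.71, Tpm3-rs7 0.92 to 1.26, Ifit1bl2 -1.68 to -1.17, Lrrc55 -1.24 to -0.91, Pdk4 -0.36 to 0.12, Angptl4 -0.44 to 0.53, Per1 -0.08 to 0.26, Per2 -0.16 to 0.29, Cry1 -0.09 to 0.16, Nr1d1 -0.13 to 0.07, Lum -0.31 to -0.23 and Xaf1 -0.29 to -0.2.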

Other observations

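No test in this part was chosen to explain a result. Gene groups outside the calls of the diet comparisons are given here as values. In C57BL/6J, Lpl, the lipase that releases fatty acids at the vessel wall, stood at -0.16 for diet (adjusted p = 0.619) and the endoplasmic reticulum chaperone gene Sdf2l1 at -0.67 (adjusted p = 0.474). Heat shock genes were lower over the list alone in 5 of 18 and higher in 1, with a list median of 0. In NZO/HlLtJ, the stress-responsive cytokine gene Gdf15 stood at 1.19 for diet (adjusted p = 0.616).

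White adipocyte marker scores differed between single libraries. They were 1.72 in the first CAST/EiJ male at 10% fat, 1.2 in the first NZO/HlLtJ male at 44% fat, -1.37 in the first C57BL/6J female at 44% fat, -1.2 in the first NZO/HlLtJ male at 10% fat and -1.09 in the first CAST/EiJ female at 10% fat. Further ribosomal protein genes differed while the sums over their copies lay close. Rpl9 stood at 156 CPM in CAST/EiJ and 6.41 in C57BL/6J, with family sums of 156 and 147 CPM. Rpl17 stood at 128 and 4.05 CPM, with sums of 129 and 134.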
